A study of Homo sapiens with 24 samples.

How the data were processed

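RNA sequencing counts per gene were analysed for 24 tumour libraries in 4 groups of 6, grouped by the treatment that the labels give each library. RNA was purified from pulverised frozen tumours with Trizol and RNeasy columns including a DNase step, and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Whether counting used strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. HISAT2 2.1.0, bedtools and edgeR are named without role or order, and the genome build as hg19 (GRCh37), per the submitters' processing notes. How reads from mouse tissue were treated is not given in the sources used here.

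The deposited table held 19267 rows, each with a gene symbol and a chromosome, and 2 kinds of column per library. The count columns hold whole-number read counts per gene that the authors did not normalize, per the file headers and the values. The TPM columns were computed by the authors, per the file headers, and sum to 288310 to 323302 over these genes, so their total was taken over a base other than the genes listed. Count divided by TPM varied between libraries by a median SD of 0.0327 on the log2 scale over 10121 genes with a mean count of at least 500. Cells listed as NaN (9.32% of the count cells) were read as 0, since no cell holds the value 0. The 8 rows of 4 symbols that appear in 2 rows each were left out, no row lacked a gene name, and no per-sample column was left unmapped. Mitochondrially encoded genes were not analysed here. Gene names and chromosomes were taken from the table; no coordinates are given, because the annotation at hand (GRCh38) is of another build than the one named by the submitters.

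Total counts ran from 36321908 to 57462006 per library, with 17199 to 17940 genes counted in each. The median SE of a log2 fold change was 0.142 for a comparison of 6 against 6 libraries and 0.201 for the interaction.

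Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The test, its samples and covariates, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), normalized with TMM factors and fitted in 1 edgeR quasi-likelihood model of 4 group means over all 24 libraries, without further covariates. The 5 contrasts were thyroid hormone and tamoxifen, each without and with the other, and their interaction, with Benjamini-Hochberg adjustment over 15689 genes and a threshold of 0.05. SEs are the fold change without prior count divided by the square root of F. Levels are CPM with TMM factors, and log2 CPM uses a prior count of 2.

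Named genes were, per contrast, the 10 highest and 10 lowest log2 fold changes among genes past the threshold with an average log2 CPM of at least 1, up to 4 members of each list with the smallest p, and ESR1, PGR, GREB1, TFF1, CCND1, MYC, MKI67, CDKN1A, THRA, THRB, KLF9 and THRSP. Where no gene passed, the 3 smallest p-values per direction were taken. ESR1 and CDKN1A passed in none of the contrasts.

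Of 27 gene lists written from general knowledge, 25 had at least 3 members tested. They cover thyroid hormone targets, receptors and transporters of the hormone, estrogen-induced and estrogen-repressed genes, cell cycle, p53, metabolism, stress, interferon and ribosome biogenesis, histone and immediate early genes, and markers of luminal, basal, fibroblast, endothelial, leukocyte, adipocyte, muscle and keratinocyte cells; red blood cell markers and mitochondrially encoded genes had fewer members tested and were left out of camera and fry. Lists were tested with camera on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Where a list passed camera's test, its median, mean and test had the same sign. Mean log2 CPM per library was compared for 7 of these lists over 28 tests by two-sided exact permutation of 6 against 6 libraries (924 splits, smallest p = 0.00216), adjusted over the 28; the other lists gave 76 further tests, of which 0 passed, among them 4 of red blood cell markers (unadjusted p = 0.0952 or more).

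The steps were tested on simulated counts with 200 genes changed by known folds. For thyroid hormone alone 56.7% of 1.5-fold, 76.1% of 2-fold and 97% of 4-fold changes were recovered, for tamoxifen alone 58.2%, 79.1% and 98.5%, for thyroid hormone with tamoxifen 50.7%, 76.1% and 98.5%, for tamoxifen with thyroid hormone 61.2%, 79.1% and 97%, and for the interaction 23.9%, 65.7% and 93.9%. Unchanged genes made up 2.99% to 8.77% of the calls. Counts were drawn independently for each gene and library, without correlation between genes, shared animals or a letter effect. The changed genes were not among those of lowest expression. All these shares may therefore be too favourable for the real libraries.

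Alternatives were RLE factors, DESeq2, limma's voom with quality weights, 2 other filters (none, and CPM of at least 1 in 6 libraries), fits of only the 2 groups compared, the replicate number as a block, the letter of the sample name or a stromal index as a covariate, E2+TH libraries that share a number in the sample name summed, other thresholds, and each library left out in turn. Added after seeing the data were a limma test on log2(TPM + 0.1), fits without the 4 libraries highest in muscle genes, lists without E2 replicate 4, and fits within each letter. Genes on chromosome Y and XIST are not reported here.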

Results

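Gene expression was measured by RNA sequencing in 24 libraries from UCD12 xenografts, a human breast tumour grown in mice. The 4 groups of 6 libraries came from tumours exposed to estradiol (E2), to estradiol with thyroid hormone (E2+TH), to estradiol with tamoxifen (E2+Tam) and to all of them together (E2+TH+Tam). Tamoxifen is a ligand of the estrogen receptor that opposes estradiol in breast tissue, and thyroid hormone acts through the nuclear receptors THRA and THRB. The study asked how thyroid hormone changes estrogen-driven growth and cell-cycle expression in receptor-positive breast tumours. Total counts per library ran from 36321908 to 45683828 in E2 and from 37493037 to 46286114 in E2+TH. They ran from 42658031 to 52079770 in E2+Tam and from 42538073 to 57462006 in E2+TH+Tam. After the filter on low counts, 15689 genes were tested. Fold changes are on the log2 scale with their standard errors (SE), with n = 6 libraries per group. Levels are CPM, read counts scaled to a common library size (mean ± SD). Adjusted p-values come from edgeR's quasi-likelihood test with the Benjamini-Hochberg method. Nothing in the labels says whether the 6 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical. E2+TH replicates 1 and 2 share a number in their sample names, and so do E2+TH replicates 5 and 6. If that number marks an animal, the p-values of comparisons with E2+TH are too small.

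The first principal component held 27.3% of the variance and the next held 13.6%. On the first, the libraries without tamoxifen lay between -42.8 and -14.3, and those with tamoxifen lay above 0 except E2+Tam replicate 1 at -22.4 and E2+TH+Tam replicate 2 at -6.91. The most similar pair of libraries, E2+TH replicates 5 and 6, still differed by 15.99 times the variance that sampling alone gives (chi-square per degree of freedom, median 98.72 over 276 pairs), so no library is a copy of another. This does not show that libraries are independent. In deviations from the group mean, Pearson's r across genes was 0.313 for E2+TH replicates 1 and 2 and 0.525 for replicates 5 and 6, against -0.589 to 0.196 for the other E2+TH pairs. Likeness was not confined to shared numbers. Replicates 1 and 4 had 0.196, 2 and 4 had 0.112, 3 and 5 had 0.187 and 3 and 6 had -0.0256. Pairs of replicate 1, 2 or 4 with replicate 3, 5 or 6 had -0.589 to -0.227. On the second principal component E2+TH replicates 1, 2 and 4 lay at -34.8, -26.4 and -27.8, and replicates 3, 5 and 6 at 17.5, 24.4 and 23.1.

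The comparison of E2+TH with E2 asks what thyroid hormone adds to estradiol alone. Known thyroid hormone responses were among the genes that rose. KLF9, a transcription factor gene on chromosome 9 that thyroid hormone induces in many tissues, rose from 14.2 ± 2.5 to 75.6 ± 46.4 CPM (log2 2.41 ± 0.37, adjusted p = 0.00145). HR, the hairless corepressor gene, rose from 124 ± 48 to 332 ± 71 CPM (1.42 ± 0.22, adjusted p = 0.00145). The metallothionein genes MT1G (1.87 ± 0.27) and MT1X (1.96 ± 0.29), both on chromosome 16, rose as well. Near-identical family members make the split of reads between these genes uncertain. Much of the size of the rises of KLF9, MT1X and MT1G came from E2+TH replicates 1, 2 and 4, where KLF9 stood at 115, 117 and 122 CPM, MT1X at 63.9, 70.8 and 39.2 CPM and MT1G at 5.64, 8.42 and 6.51 CPM. The other E2+TH libraries had 31.9 to 34.6, 19.8 to 23.6 and 2.48 to 4.09 CPM, still above every E2 library (at most 17.8, 13.1 and 1.57 CPM). HEG1 rose by 1.92 ± 0.31 and PRSS27 by 1.77 ± 0.27, whereas WNT2B (-1.90 ± 0.33), UPK1A (-1.89 ± 0.32), the zinc transporter gene SLC30A2 (-1.88 ± 0.32) and IGDCC3 (-1.98 ± 0.39) fell. CYP1A1, which encodes a xenobiotic-metabolising oxygenase, rose by 3.23 ± 0.68 from 0.129 ± 0.059 CPM (adjusted p = 0.0128).

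Of the 14 thyroid hormone target genes tested, 2 rose and none fell over all genes (4 rose and 1 fell when adjusted over the list alone), with a median of 0.353 (camera adjusted p = 0.00396, and adjusted p = 0.259 with an estimated correlation). THRSP, a lipogenesis regulator gene, had 1.72 ± 0.54 (adjusted p = 0.0856) and did not pass. Among the 17 genes for receptors, transporters and cofactors of the hormone, 2 fell, RXRA (-0.55) among them, and 7 fell with 1 rising when adjusted over the list alone. The call of RXRA (adjusted p = 0.0436) ended in 7 of 12 refits leaving out 1 library (adjusted p up to 0.117, without E2+TH replicate 4). The list's median was -0.284 (camera adjusted p = 0.00205, and adjusted p = 0.259 with an estimated correlation). The receptor genes had -0.46 ± 0.18 for THRA and -0.46 ± 0.14 for THRB, with adjusted p = 0.155 and 0.0665.

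Cell-cycle genes moved upward as groups, by small amounts. All 49 DNA replication and G1/S genes had a fold change above 0, with a median of 0.338 (camera adjusted p = 3.72e-16, and adjusted p = 0.281 with an estimated correlation). Over all genes 1 of them rose, the chromatin assembly gene CHAF1B (0.48 ± 0.12, adjusted p = 0.0388), and 15 rose when adjusted over the list alone. The call of CHAF1B ended in 9 of 12 refits leaving out 1 library (adjusted p up to 0.105, without E2+TH replicate 4). The 50 G2/M and mitosis genes also lay above 0 without exception, with a median of 0.343 (camera adjusted p = 6.29e-14, and adjusted p = 0.349 with an estimated correlation). None passed alone, either over all genes or adjusted over the list alone. The proliferation marker gene MKI67 had 0.44 ± 0.23 (adjusted p = 0.284) and MYC had 0.45 ± 0.31 (adjusted p = 0.433). The mean log2 CPM of the G1/S list was 0.405 higher in E2+TH than in E2 (exact permutation p = 0.0108, adjusted p = 0.0433). The G2/M list was 0.416 higher (exact permutation p = 0.0108, adjusted p = 0.0433). Both differences rested in part on E2 replicate 4, the E2 library lowest in both lists: without it they were 0.215 and 0.187, each with adjusted p = 0.0682 in the exact permutation test. The thyroid hormone target list stood 0.507 higher in E2+TH, above the E2 mean in 6 of 6 libraries (exact permutation p = 0.00216, the smallest that 6 against 6 libraries can give, adjusted p = 0.0303). It kept an adjusted p = 0.0485 without E2 replicate 4 in the exact permutation test. All these differences missed the threshold when E2+TH libraries whose sample names share a number were averaged (exact permutation adjusted p = 0.101 for the target list, 0.311 for G1/S and 0.364 for G2/M). Averaging left 4 E2+TH values in place of 6, and the differences stayed about as large at 0.527, 0.413 and 0.41.

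Further lists passed camera's test with few members passing alone. Upward were the replication-dependent histone genes (18 tested, 1 rose, median 0.487, adjusted p = 4.45e-06), whose near-identical copies make single members uncertain, and ribosome biogenesis and MYC target genes (32 tested, 3 rose, 0.206, adjusted p = 1.37e-08). The same held for oxidative phosphorylation genes (49 tested, 1 rose, COX6C at 0.93 ± 0.20; median 0.152, adjusted p = 4.79e-07) and interferon-stimulated genes (38 tested, 1 rose, ISG20 at 0.80 ± 0.13; median 0.385, adjusted p = 2.57e-07). Also upward were p53 target genes (23 tested, 3 rose, 0.184, adjusted p = 0.00067), unfolded protein response genes (24 tested, 2 rose, 0.122, adjusted p = 0.0128) and immediate early genes (0.275, adjusted p = 0.022). Over all genes no member passed among the fatty acid synthesis genes (2 rose when adjusted over the list alone, median 0.124, adjusted p = 0.0381), cholesterol synthesis genes (0.145, adjusted p = 0.0447) and glycolysis and hypoxia genes (0.134, adjusted p = 0.0349), whose lists were higher. Downward were fibroblast and matrix markers (-0.51, adjusted p = 0.00595) and basal and progenitor markers (-0.336, adjusted p = 0.0447). None of these held with an estimated correlation, where the smallest adjusted p = 0.259 over the 25 lists. Without E2 replicate 4 the calls ended for cholesterol synthesis (adjusted p = 0.105), fatty acid synthesis (adjusted p = 0.105) and glycolysis genes (adjusted p = 0.213). Skeletal muscle markers moved with the group too, at a median of 1.34 (camera adjusted p = 0.0447, 0.576 with an estimated correlation, and 0.0716 without E2 replicate 4). The estrogen-induced genes did not pass (36 tested, 1 rose, median 0.133, adjusted p = 0.168). GREB1 had -0.08 ± 0.37, TFF1 0.57 ± 0.29, PGR -0.53 ± 0.53 and CCND1 -0.04 ± 0.25. Estrogen-repressed genes, CDK inhibitors and G1 regulators, and luminal, endothelial, macrophage and leukocyte, adipocyte and keratinocyte markers did not pass either (adjusted p = 0.0512 or more). The endothelial list passed, downward, without E2 replicate 4 (adjusted p = 0.0219). The tumours grew in mice, and whether reads of fibroblast, endothelial, leukocyte or muscle markers came from human or mouse cells was not tested.

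In all, 163 genes rose and 236 fell with thyroid hormone alone, 106 of these 399 by at least 2-fold. With the E2+TH libraries that share a number in the sample name summed, 155 genes were called. Of the 20 genes with the largest changes, 12 passed in each of 12 refits that left out 1 library. The others, CALML5, CGA, COL2A1, IKZF2, LHX1, NECAB1, PHEX and TGM4, lost their call in some, with adjusted p up to 0.114 for LHX1 without E2 replicate 4. The count fell to 186, 249, 175 and 259 without E2 replicates 1, 4, 5 and 6. It was 173, 168, 258 and 166 without E2+TH replicates 1, 2, 3 and 4, and 731 without E2 replicate 2. Sample names carry a letter, L or R, of unstated meaning. Among R libraries alone (5 E2 and 3 E2+TH), 8 genes were called. With the letter as a covariate 864 were called. No test was run among L libraries, where E2 would rest on a single library.

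The comparison of E2+Tam with E2 asks what tamoxifen does to estradiol-exposed tumours. Genes known to be driven by the estrogen receptor fell. PRSS23 fell from 179 ± 127 to 21.0 ± 7.3 CPM (-3.09 ± 0.47, adjusted p = 0.000693). IGFBP4, which encodes a binding protein of insulin-like growth factors, fell from 250 ± 96 to 69.6 ± 25.1 CPM (-1.84 ± 0.29, adjusted p = 0.000937). SGK3 fell by 1.86 ± 0.31 and SUSD3 fell by 1.71 ± 0.33. TFF1 fell from 446 ± 126 to 214 ± 68 CPM (-1.06 ± 0.29, adjusted p = 0.0424). This call ended in 10 of 12 refits leaving out 1 library (adjusted p up to 0.112, without E2 replicate 3). GREB1 had -1.26 ± 0.38 (adjusted p = 0.066) and did not pass. Over the list, 7 of 36 estrogen-induced genes fell and none rose (11 fell and 2 rose when adjusted over the list alone), with a median of -0.331 (camera adjusted p = 0.00072, and adjusted p = 0.729 with an estimated correlation). The mean level of the list was 0.412 lower on the log2 scale, 5.93 ± 0.17 in E2+Tam against 6.34 ± 0.32 in E2 (exact permutation p = 0.0108, adjusted p = 0.0433, and 0.0485 without E2 replicate 4). The call ended when E2+TH libraries sharing a number were averaged in the other comparisons, through the shared adjustment (exact permutation adjusted p = 0.101).

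Other genes rose with tamoxifen. The keratin gene KRT13 rose by 3.74 ± 0.45 (adjusted p = 9.22e-05) and ATP4A, which encodes the catalytic subunit of the gastric proton pump, by 5.19 ± 0.66 from 0.149 ± 0.108 to 5.47 ± 3.10 CPM (adjusted p = 0.000109). NTRK2 (4.12 ± 0.78), SLC34A2 (3.29 ± 0.52), MAP6 (3.23 ± 0.47) and COLEC12 (2.97 ± 0.44) also rose, and C6orf141 (-3.37 ± 0.45) and ELOVL2 (-2.14 ± 0.38) fell. CRYM, whose product binds thyroid hormone in the cytosol, rose by 1.74 ± 0.37. The list that holds it did not pass (2 of 17 rose, camera adjusted p = 0.758).

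Cell-cycle lists did not pass in this comparison: the median was -0.0719 for the G1/S list (camera adjusted p = 0.859) and -0.078 for the G2/M list (adjusted p = 0.691), with no member past the test, and MKI67 had -0.13 ± 0.23. This rested in part on E2 replicate 4. Without it both lists were lower with tamoxifen by camera at the preset correlation (adjusted p = 8.78e-06 and 1.11e-09). The differences of their mean levels moved from 0.0148 to -0.175 for G1/S and from -0.0114 to -0.24 for G2/M. In the exact permutation test these had p = 0.0736 and 0.039 without it, and did not pass after adjustment (adjusted p = 0.159 and 0.109). Camera with an estimated correlation and fry were not run without this library. Glycolysis and hypoxia genes were higher (32 tested, 2 rose, median 0.202, adjusted p = 0.000125). Fatty acid synthesis (-0.302, adjusted p = 0.0341), ribosome biogenesis (-0.0834, adjusted p = 0.0288) and histone genes (-0.365, adjusted p = 0.0288) were lower. So were unfolded protein response genes (-0.105, adjusted p = 0.0412, and 0.102 without E2 replicate 4) and fibroblast markers (-0.681, adjusted p = 0.0288, although 1 member, THY1, rose). Skeletal muscle markers were higher (median 1.15, 1 of 15 rose, adjusted p = 0.0105). With an estimated correlation none of the 25 lists passed, the smallest adjusted p = 0.729.

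With tamoxifen alone 352 genes rose and 173 fell, 295 of these 525 by at least 2-fold. Of the 20 genes with the largest changes, 14 passed in every refit without 1 library, and ADAM29, ANK1, CCNA1, COL21A1, GLRA3 and MPPED1 did not (adjusted p up to 0.0928, for CCNA1 without E2+Tam replicate 3). The count was 248, 332 and 308 without E2 replicates 3, 5 and 6 and 262, 230 and 294 without E2+Tam replicates 3, 4 and 5. It reached 879 without E2+Tam replicate 1 and 804 without the 4 libraries highest in muscle genes. The letter of the sample name nearly followed these groups, with 1 L library in E2 and 1 R library in E2+Tam, so no test was run within a letter, where 1 of the groups would hold a single library. With the letter as a covariate 135 genes were called, 54 higher and 81 lower. A limma test on log2 TPM called 328, of which 54.6% were higher, against 67% on counts.

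**Figure D1:**
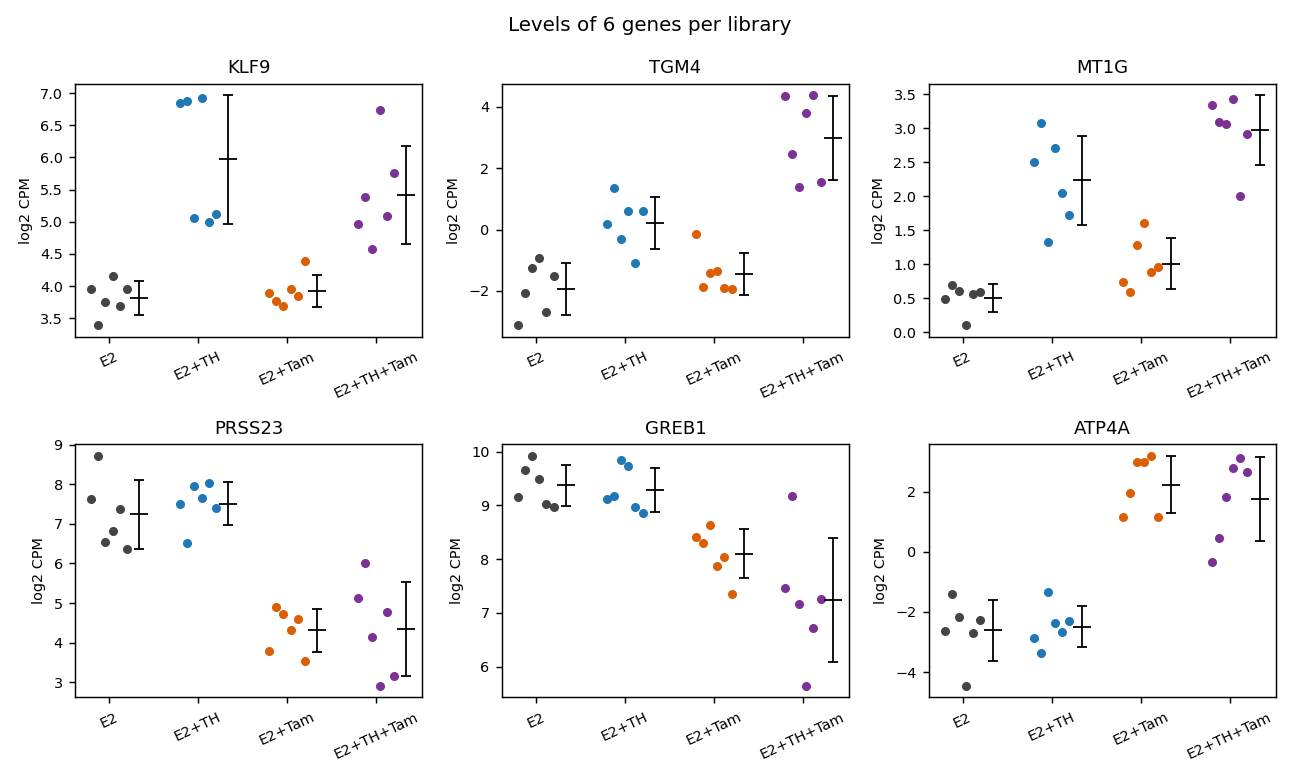
Level of KLF9, TGM4, MT1G, PRSS23, GREB1 and ATP4A in each library, as log2 CPM, by group; points are libraries (6 per group) and the black bar beside them is the mean ± SD. KLF9 and MT1G are higher in both groups with thyroid hormone, and PRSS23 is lower and ATP4A higher in both groups with tamoxifen.

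The comparison of E2+TH+Tam with E2+Tam asks whether thyroid hormone acts on tumours already exposed to tamoxifen. TGM4, a transglutaminase gene on chromosome 3, rose from 0.365 ± 0.249 to 11.1 ± 8.6 CPM (4.92 ± 0.61, adjusted p = 0.000196). Other genes that rose were THRSP (3.06 ± 0.58, adjusted p = 0.00531), KLF9 (1.67 ± 0.36, adjusted p = 0.0128), MT1G (2.01 ± 0.27, adjusted p = 0.000295), SLC37A2 (2.09 ± 0.32), C2orf54 (2.03 ± 0.33) and CYP1A1 (3.98 ± 0.78). Genes that fell included IGDCC3 (-2.45 ± 0.39, adjusted p = 0.0017) and UPK1A (-1.95 ± 0.31). Of 14 thyroid hormone target genes, 3 rose (KLF9, THRSP and the malic enzyme gene ME1 at 0.85 ± 0.17) and none fell. Adjusted over the list alone, 4 rose and 1 fell. The list did not pass camera's test (median 0.0704, adjusted p = 0.0521), with 7 of 14 members above 0. Its mean level was 0.427 higher, in 6 of 6 libraries (exact permutation p = 0.00216, adjusted p = 0.0303), a shift carried by few members. With E2+TH libraries sharing a number averaged in the other comparisons, the shared adjustment gave an adjusted p = 0.0606 in the exact permutation test.

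Among 15 fatty acid synthesis genes 3 rose, ELOVL5 (0.70 ± 0.14) among them, with a median of 0.233 (camera adjusted p = 0.00097, and adjusted p = 0.502 with an estimated correlation). The G2/M list had a median of 0.211 with 1 member rising, KIF15 at 0.67, and 3 when adjusted over the list alone (camera adjusted p = 0.000185, and adjusted p = 0.648 with an estimated correlation). The call of KIF15 (adjusted p = 0.0443) ended in 10 of 12 refits (adjusted p up to 0.105, without E2+Tam replicate 3). The G1/S list had a median of 0.0982 with no member past the test (camera adjusted p = 0.018, and adjusted p = 0.737 with an estimated correlation). Their mean levels did not differ past the threshold (exact permutation p = 0.119 and 0.262). Ribosome biogenesis (2 rose, 0.134, adjusted p = 4.93e-05), histone (3 rose, 0.539, adjusted p = 1.04e-05), oxidative phosphorylation (1 rose, 0.108, adjusted p = 0.000411), cholesterol synthesis (1 rose, 0.143, adjusted p = 0.00559) and p53 target genes (1 rose, 0.146, adjusted p = 0.0125) were higher by camera's test. Glycolysis genes (1 fell, -0.218, adjusted p = 0.000411) and luminal markers (-0.147, adjusted p = 0.0137) were lower. So were skeletal muscle markers (none past over all genes, 8 of 15 fell when adjusted over the list alone, -0.918, adjusted p = 0.00326). With an estimated correlation no list passed, the smallest adjusted p = 0.414. The estrogen-induced list did not pass (1 rose, 3 fell, camera adjusted p = 0.611). RERG fell by 0.99 ± 0.22, whereas GREB1 had -0.50 ± 0.37 and TFF1 0.67 ± 0.29.

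With thyroid hormone on top of tamoxifen 212 genes rose and 357 fell, 175 of these 569 by at least 2-fold. In every refit without 1 library 14 of the 20 with the largest changes passed, and COL2A1, MAPK4, NECAB1, PCDH7, SATB1 and SIGLEC6 did not (adjusted p up to 0.0999, for SATB1 without E2+TH+Tam replicate 5). The count fell to 340, 197, 235 and 369 without E2+Tam replicates 1, 2, 3 and 5 and to 226 and 213 without E2+TH+Tam replicates 1 and 2. It was 84 without the 4 libraries highest in muscle genes, a setting chosen after seeing the data that removes E2+Tam replicates 1 and 2. Among L libraries alone (5 against 4) 23 genes were called. No test was run among R libraries, where E2+Tam would rest on a single library.

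The comparison of E2+TH+Tam with E2+TH asks what tamoxifen does in the presence of thyroid hormone. ATP4A rose by 4.90 ± 0.65. PRSS23 fell by 2.85 ± 0.47, IGFBP4 by 1.89 ± 0.29 and ANK1 by 3.14 ± 0.51. GREB1, an estrogen-induced growth regulator gene, fell from 648 ± 194 to 202 ± 191 CPM (-1.68 ± 0.38, adjusted p = 0.0074). TFF1 fell by 0.96 ± 0.29 (adjusted p = 0.0402), a call that ended in 8 of 12 refits (adjusted p up to 0.12, without E2+TH replicate 1). In all, 12 of 36 estrogen-induced genes fell and none rose, SIAH2 (-0.96 ± 0.19) and RERG (-1.11 ± 0.22) among them. Adjusted over the list alone 15 fell and 1 rose. The list's median was -0.462 (camera adjusted p = 5.3e-07, and adjusted p = 0.685 with an estimated correlation). Its mean level was 0.529 lower (exact permutation p = 0.00866, adjusted p = 0.0433, and 0.133 with E2+TH libraries sharing a number averaged, where the difference was -0.6 with 4 E2+TH values).

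Of 49 G1/S genes 4 fell and none rose, both over all genes and adjusted over the list alone, among them the replication licensing gene MCM2 (-0.52 ± 0.14, adjusted p = 0.0209, and 0.065 without E2+TH+Tam replicate 5) and CHAF1A (-0.41 ± 0.10, adjusted p = 0.0128). The median was -0.277 (camera adjusted p = 1.07e-07, and adjusted p = 0.859 with an estimated correlation). The mean level was 0.279 lower (exact permutation p = 0.00866, adjusted p = 0.0433, and 0.16 with the averaged libraries, where the difference was -0.287). The G2/M list had a median of -0.218 with no member past the test (camera adjusted p = 0.000544, and adjusted p = 0.967 with an estimated correlation). Its level did not pass (exact permutation p = 0.0736, adjusted p = 0.206). Immediate early genes (1 fell, EGR2 at -1.80 ± 0.45, median -0.469, adjusted p = 0.00161) and ribosome biogenesis genes (2 fell, -0.135, adjusted p = 0.00107) were lower. Unfolded protein response (2 fell, -0.104, adjusted p = 0.015), p53 target (2 fell, -0.171, adjusted p = 0.0167) and interferon-stimulated genes (1 fell, -0.174, adjusted p = 0.0167) were lower too. The list of hormone receptors and transporters was higher (CRYM rose by 2.05 ± 0.38, median 0.219, adjusted p = 0.0268). None held with an estimated correlation, where the smallest adjusted p = 0.685.

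Further gene groups also had large fold changes in this comparison. CCNA1, a cyclin gene, rose by 5.06 ± 0.95 and SATB1 by 4.04 ± 0.77. EFCAB1, SNTN, ARMC4, TEKT1, C11orf88 and CAPSL, genes of motile cilia or expressed with them, rose by 3.97 to 4.56. The myosin genes MYH1 (-7.29 ± 2.02), MYH2 (-6.69 ± 1.92) and MYH4 (-7.19 ± 2.06), close paralogs whose reads may be split uncertainly, and DES (-2.92) fell, calls that ended in 2 to 8 of 12 refits (adjusted p up to 0.108, for DES without E2+TH replicate 5). Their level was high in E2+TH replicates 3 and 5. Of 15 skeletal muscle markers 6 fell and 1 rose (camera adjusted p = 0.0693).

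With tamoxifen on top of thyroid hormone 835 genes rose and 446 fell, 613 of these 1281 by at least 2-fold. Among the 20 with the largest changes 13 passed in every refit without 1 library, and ADAM29, ARHGAP36, DES, MYH1, MYH2, MYH4 and PCSK1 did not (adjusted p up to 0.108, for DES without E2+TH replicate 5). The count was 785 without E2+TH+Tam replicate 5. Within letters it was 494 among L libraries (3 against 4) and 3 among R libraries (3 against 2). With the E2+TH libraries that share a number summed it was 828.

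**Figure D2:**
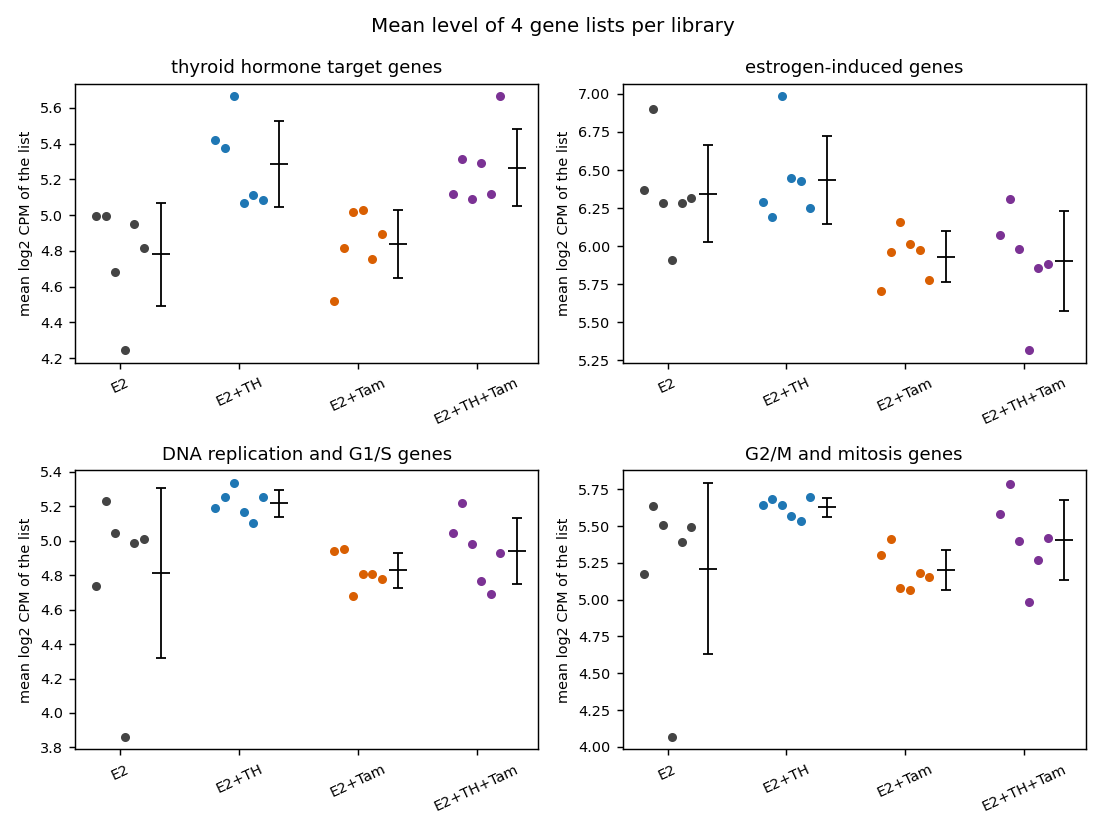
Mean log2 CPM of the thyroid hormone target, estrogen-induced, G1/S and G2/M lists in each library, by group; points are libraries (6 per group) and the black bar beside them is the mean ± SD. The target list is higher in both groups with thyroid hormone, the estrogen-induced list is lower in both groups with tamoxifen, and E2 replicate 4 has the lowest G1/S (3.86) and G2/M (4.07) means of the E2 libraries.

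Does either treatment act differently when the other is present? No gene passed edgeR's test of this interaction (smallest adjusted p = 0.763), with 982 genes at an unadjusted p under 0.05 against 784 by chance. DESeq2 called 1, RBM20 (3.12, adjusted p = 0.00418), and limma's voom with quality weights called 0. The smallest p-values belonged to RBM20 (3.12 ± 0.63), SATB1 (3.87 ± 1.01) and RAB7L1 (1.14) upward and HSH2D (-0.70), TLE1 (-0.57) and FAM43A (-1.25) downward, none past the test. KLF9 had -0.74 ± 0.50 and GREB1 -0.43 ± 0.53. In simulated counts, where many genes were changed at once by known folds, the same test recovered 65.7% of 2-fold and 23.9% of 1.5-fold interactions. The adjusted threshold is easier to pass when many genes change. No gene passed here, so these shares may be too high for these data. Interactions of 1.5-fold would mostly be missed. Those of 2-fold can be missed too, since 65.7% of them were recovered in the simulated counts. RBM20, at 3.12 ± 0.63, was picked for its small p, so whether it is a missed interaction is not settled.

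The direction of change was shared between backgrounds. Of the 399 genes called for thyroid hormone alone, 382 (95.7%) had the same sign with tamoxifen present, and 132 were called in both settings, 43 higher (2.2 if the lists were independent) and 89 lower (5.37). For tamoxifen, 516 of 525 genes (98.3%) kept their sign with thyroid hormone present and 290 were called in both, 190 higher (18.7 if independent) and 100 lower (4.92), with none opposite for either treatment. Across genes, which are not independent replicates, the fold changes of thyroid hormone in the 2 backgrounds had Pearson's r = 0.362 (Spearman's rho 0.379, jackknife SE of r 0.111 over libraries) and those of tamoxifen r = 0.644 (rho 0.474, SE 0.12). No library enters both comparisons of a pair.

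**Figure D3:**
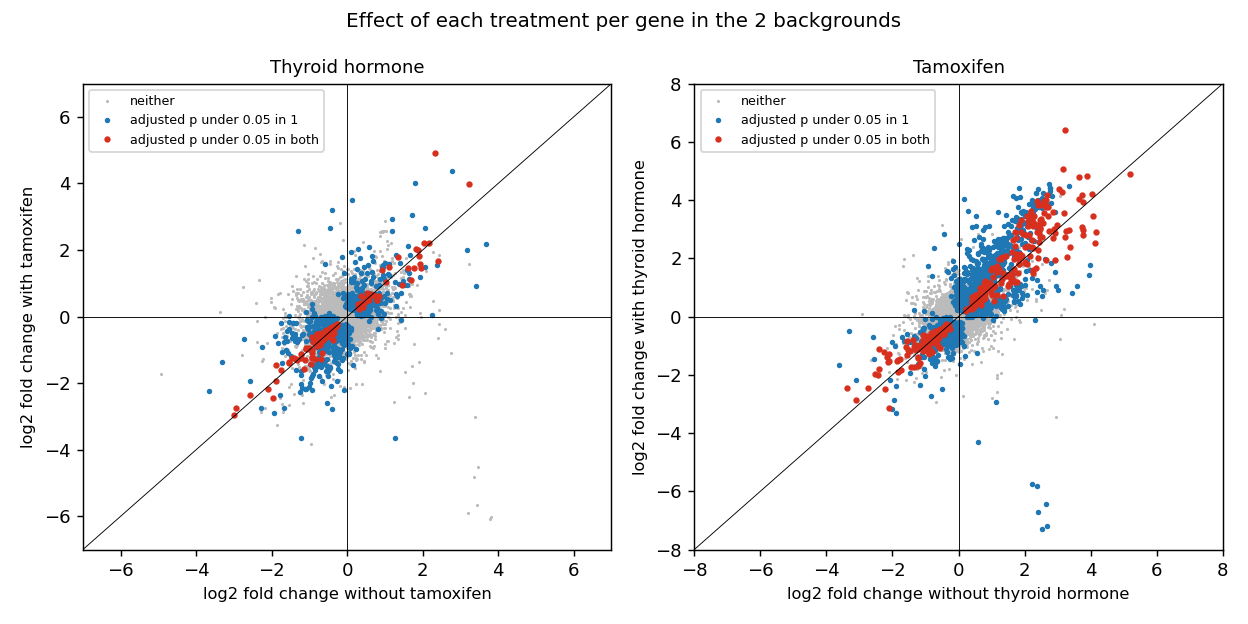
Log2 fold change of each gene for thyroid hormone (left) and tamoxifen (right), without the other treatment on the horizontal axis and with it on the vertical axis; grey genes passed neither test, blue 1 and red both, and the line marks equal changes. The 132 genes red for thyroid hormone and the 290 red for tamoxifen all lie in the quadrants of equal sign.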

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

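In this part the tests of a wrong label and of depth for E2 replicate 4, both tests of the muscle genes, and the lists without E2 replicate 4 were chosen after the result was seen; the test of the letter for E2 replicate 4 and the counts of calls over other splits of the samples were set before, and the balance of letters in those splits was looked at after. Of 184 groups of 6 values examined, 20 had 1 library far from the others (gap to the nearest over the whole range above Dixon's critical value), and chance alone gives about 1 in 20 groups, or 9.2.

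E2 replicate 4 was the lowest E2 library in cell-cycle expression: 3.86 in mean log2 CPM of the G1/S list (others 4.74 to 5.23), 4.07 in the G2/M list (5.17 to 5.64), 5.2 in log2 CPM of MKI67 (6.67 to 7.22) and 7.67 in CCND1 (9.04 to 9.74), and also 6.29 in fatty acid synthesis genes (6.5 to 6.61), 1.81 in adipocyte markers (2.22 to 2.43) and 0.104 in MT1G (0.494 to 0.692). A tamoxifen tumour under a wrong label is argued against by the 446 genes that fell with tamoxifen in the presence of thyroid hormone, a comparison without E2 libraries: their mean log2 CPM was 4.78 in this library, at the lower end of the other E2 libraries (4.78 to 5.01) and above E2+Tam (4.3 to 4.61); the 835 genes that rose averaged 2.07, inside E2+Tam (1.82 to 3.05) and above the other E2 libraries (1.57 to 1.77), so part of its profile remains unexplained by its label. Low depth is argued against by its total of 37.9 M counts, since E2 replicate 2 had 36.3 M. The letter of the sample name stays open, as this is the only L library of its group, so library and letter cannot be told apart. Its deviation correlated across genes with the L minus R difference at r = 0.267 within E2+TH+Tam and 0.325 within E2+TH. These 2 differences correlated with each other at r = 0.112. They rest on 4 L against 2 R and on 3 against 3 libraries, so this cannot decide how much of a letter difference the groups share. No biological explanation was tested, because the labels give no difference among E2 tumours.

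Skeletal muscle genes were high in single libraries of 3 groups: the list's mean log2 CPM was 1.94 in E2 replicate 3 (other E2 libraries -0.437 to 0.0711), and MYH1 reached 22.6 and 32 CPM in E2+TH replicates 3 and 5 and 9.5 and 12.8 CPM in E2+Tam replicates 1 and 2, where ACTA1 stood at 29.5, 33.4, 15.7 and 28.1 CPM. Reads from muscle tissue in those samples are a candidate source that stays open. After group means were removed, the 15 list members tested (of 18 written) had a median pairwise Spearman rho of 0.647, against at most 0.269 in 1000 random lists of matched expression, but this restates that they were high in the same libraries and does not decide the source. MB (28.5 to 75 CPM) and TTN (7.38 to 16.5 CPM) were counted in every library. An effect of treatment on the list stays open, since the smallest adjusted exact permutation p over the 4 comparisons was 0.154, which does not exclude a difference. Whether such reads came from human or mouse cells was not tested.

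The remaining single values are given without explanation. E2+TH+Tam replicate 4 had the highest total, 57.5 M counts (others 42.5 to 46), and the lowest luminal markers, 8.23 (8.47 to 8.61). Estrogen-induced genes averaged 6.98 in E2+TH replicate 3 (6.19 to 6.45), where THRSP stood at 2.71 (-0.0464 to 0.983). Estrogen-repressed genes averaged 5.4 in E2+Tam replicate 6 (5.63 to 5.74), and KLF9 was 4.4 there (3.69 to 3.95). In E2 replicate 2, PGR was 4.21 (2.04 to 2.65) and THRB 3.62 (4.42 to 4.67). MYC was 5.01 in E2+TH replicate 4 (6.67 to 7.21). TGM4 was -0.144 in E2+Tam replicate 1 (-1.94 to -1.35). In E2+TH+Tam replicate 5, MT1G was 2.01 (2.91 to 3.43) and MT1X 4.2 (5.34 to 5.65).

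By camera's test of the interaction, 7 lists differed in their response to one treatment between the backgrounds. Lower with both treatments than the sum of the single effects were G1/S genes (median log2 -0.23, adjusted p = 1.23e-08), G2/M genes (-0.137, adjusted p = 0.00109), glycolysis and hypoxia genes (-0.339, adjusted p = 1.1e-08), interferon-stimulated genes (-0.321, adjusted p = 1.57e-05) and skeletal muscle markers (-2.02, adjusted p = 6.77e-07). Higher were receptors and transporters of thyroid hormone (0.209, adjusted p = 0.0443) and fibroblast and matrix markers (0.431, adjusted p = 0.048). With an estimated correlation each had an adjusted p = 0.831, and fry passed 0 lists. Without E2 replicate 4 the G2/M list turned upward (adjusted p = 0.778) and the receptor list lost its call (adjusted p = 0.135).

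Other splits of the same 12 libraries, 100 per comparison with the real one included, were fitted to see whether chance gives as many genes. For thyroid hormone alone 4 splits gave at least the real 399, the highest other 1059; for tamoxifen alone 1 split did (real 525, highest other 127); for thyroid hormone with tamoxifen 2 did (real 569, highest other 694); and for tamoxifen with thyroid hormone 1 did (real 1281, highest other 1127). The labels do not say whether the libraries of a group came from separate animals. If they did, chance can be excluded by the number of calls for both comparisons without E2+TH (share under 0.05, unadjusted). For tamoxifen alone this does not tell tamoxifen from the letter of the sample name. For the comparisons with E2+TH the exclusion also holds only if its libraries are independent, narrowly for thyroid hormone alone. The real split keeps together the E2+TH libraries that share a number in the sample name, which other splits can part, so these shares would otherwise be too small. By the number of genes at an unadjusted p under 0.05, 5, 1, 4 and 4 of 100 splits reached the real 3067, 2731, 2996 and 3600, so for thyroid hormone alone chance is not excluded by that number. Why some other splits called more genes than the real one was not settled. For thyroid hormone with tamoxifen the letter may contribute: the split with 694 calls put all R libraries into 1 group, and 7 of 17 such splits called genes against 4 of 82 others, while 543 genes were called with the letter as a covariate. For thyroid hormone alone the split with 1059 calls was no less balanced in letters than the real one. For tamoxifen alone the real split holds 1 L library against 5. Of 8 other splits with the same difference in letters, 2 called genes (highest 127). Among splits with a smaller difference, 1 of 50 and 0 of 41 did. For the interaction the real count of 0 is reached by all 100 splits whatever they give (highest other 174, from splits of the 24 libraries), so that count decides nothing. The real 982 genes at an unadjusted p under 0.05 were reached by 39 of 100 splits, so chance cannot be excluded.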

How the results depend on the processing

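Of 170 named calls none reversed under the alternatives that tested them, which were 94 or 95 calls within a letter. Over all calls, 1269 of 1280 kept their sign among R libraries for tamoxifen with thyroid hormone. RLE factors and DESeq2 kept 170, voom with quality weights 149, no filter 160, the letter covariate 146, the stromal covariate 158 and summed E2+TH libraries 138. Log2 TPM kept 119, fits of 2 groups 128 of 166, the sets without the 4 libraries highest in muscle genes 121 of 168, L libraries 42 of 95 and R libraries 5 of 94 (fewer libraries). The settings on TPM, muscle libraries, single letters and lists without E2 replicate 4 were chosen after the data were seen. Where counts moved by over 1.5 times, the cause was not tested unless stated.

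For thyroid hormone alone (399 genes) DESeq2 called 870, voom 1077, the letter covariate 864, a fit of only the 2 groups 176, summed E2+TH libraries 155 (fewer libraries) and R libraries 8 (fewer libraries). For tamoxifen alone (525) DESeq2 called 1040, voom 2666, the letter covariate 135, log2 TPM 328 and the set without muscle-high libraries 804. For thyroid hormone with tamoxifen (569) DESeq2 called 1095, voom 2073, the fit of 2 groups 343, the stromal covariate 922, the set without muscle-high libraries 84 and L libraries 23. For tamoxifen with thyroid hormone (1281) the fit of 2 groups called 812, summed E2+TH libraries 828, L libraries 494 and R libraries 3. A 2-fold minimum left 106, 295, 175 and 613 genes, and an adjusted p under 0.1 gave 916, 1043, 1142 and 2001, by construction. Log2 TPM moved the share of higher calls from 67% to 54.6% for tamoxifen alone, from 65.2% to 76% with thyroid hormone and from 37.3% to 51.4% for thyroid hormone with tamoxifen. The interaction (0) had 1 call by DESeq2 (RBM20) and 4 with the stromal covariate (TNNT3, MYH4, MYH1 and HSH2D). Leaving out 1 library gave 166 to 731, 230 to 879, 197 to 793 and 785 to 1540 genes, and 0 to 0 for the interaction.

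With the replicate number as a block 544, 530, 610 and 1443 genes were called, and 156 of 170 named calls stayed. Whether the replicate numbers pair the libraries is not settled. The 36 same-numbered pairs had a mean correlation of 0.0831 (-0.297 to 0.532), somewhat above the -0.0165 of others. Of 24 libraries, 9 correlated best with their own number. The block changed 1 of 125 list calls, muscle markers for tamoxifen with thyroid hormone (adjusted p = 0.0314). With summed E2+TH libraries 4 list calls by camera's test ended and 4 were gained. With the stromal covariate, where marker lists were left out, 4 ended and 6 were gained.

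Of the 17, 8, 11, 9 and 7 lists past camera's test, 0 passed in each contrast with an estimated correlation and 8, 0, 2, 1 and 0 with fry. Of 7 list levels past the exact permutation test, 0 passed with E2+TH libraries sharing a number averaged, although the 5 differences with E2+TH stayed about as large (0.527, 0.413, 0.41, -0.6 and -0.287, with 4 E2+TH values in place of 6) and the other 2 hold no E2+TH library. Without E2 replicate 4, 6 of 125 list calls ended, 5 were gained, and G2/M in the interaction reversed (adjusted p = 0.778, upward). The correlation across genes of thyroid hormone effects was 0.738 over the 836 genes called in either background, which selects large changes. Alternative pseudocounts planned for normalized values were not run, since the values are counts.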

Other observations

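The cilium and metallothionein lists of this part, the tests of tamoxifen treatment and of the letter, and the genes named at its end were chosen after their values were seen; the test of cycling cells was set before its result.

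Genes of motile cilia, the beating cell projections of multiciliated epithelium, were higher with tamoxifen. A list of 31 tested members, written without the cilium genes that had led to it, had 9 members that rose and none that fell with tamoxifen alone (median log2 1.33) and 27 that rose and none that fell with thyroid hormone present (median 2.1). FOXJ1, the master regulator gene of motile ciliogenesis, rose by 2.30 (adjusted p = 0.0289) and 3.47 (adjusted p = 0.00122). No member passed for thyroid hormone or for the interaction. As a group 30 of 31 members lay above 0 for thyroid hormone with tamoxifen (median 0.614, camera unadjusted p = 1.15e-06, and 0.282 with an estimated correlation) and 29 of 31 for the interaction (median 0.879, camera unadjusted p = 1.37e-05, and 0.334 with an estimated correlation). Camera with an estimated correlation gave an unadjusted p = 0.119 and 0.0382 for the 2 tamoxifen comparisons.

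Metallothionein genes encode metal-binding stress proteins. MT1G and MT1X, whose rise with thyroid hormone led to the list, were left out, which leaves MT1E, MT1F, MT1M and MT2A. The mean log2 CPM of these 4 was higher by 0.825 for tamoxifen, 0.711 for thyroid hormone with tamoxifen and 1.07 for tamoxifen with thyroid hormone, in 6 of 6 libraries each (adjusted exact permutation p = 0.00866 for each). For thyroid hormone alone it was 0.464 higher, in 5 of 6 libraries, and did not pass (adjusted p = 0.182). Of the 4, 1 rose in each tamoxifen comparison, 1 for thyroid hormone alone and 0 for thyroid hormone with tamoxifen. Over all 6 tested members the differences were 0.717 and 0.856 for tamoxifen without and with thyroid hormone (adjusted exact permutation p = 0.00577 and 0.0173). For thyroid hormone without and with tamoxifen they were 0.897 and 1.04 (adjusted p = 0.0208 and 0.00577). Leaving out MT1G and MT1X thus raised the former and lowered the latter. The letter of the sample name nearly follows E2+Tam against E2, so it cannot be told apart from tamoxifen there. Camera with an estimated correlation, over all 6 tested members, gave an unadjusted p = 0.0837 and 0.0717 for the 2 tamoxifen comparisons, so these did not pass. Reads shared between near-identical members make single genes uncertain.

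An effect of tamoxifen on cilium genes may underlie the pattern: the list's mean log2 CPM was higher by 1.29 without thyroid hormone, in 5 of 6 libraries, and by 2.01 with it, in 6 of 6 (adjusted exact permutation p = 0.0462 and 0.00577). A lower share of cycling cells stays open. With the G1/S level as a covariate 82.4% of the median change with thyroid hormone present stayed (2.1 to 1.73, 23 of 27 calls kept). This cannot decide, because E2 replicate 4, outside that comparison, weighs heavily in the covariate (3.86, all other libraries 4.68 to 5.34). The same library had the highest cilium list level of those without tamoxifen (3.39 in mean log2 CPM, others 1.63 to 2.48). The letter of the sample name is argued against for E2+TH+Tam against E2+TH, where 90.6% of the median stayed with the letter as a covariate and 26 of 27 calls were kept. For E2+Tam against E2 the letter cannot be told apart from tamoxifen, because it nearly follows the groups: 56% of the median stayed (1.33 to 0.742, interquartile range 0.335 to 1.18) and all 9 calls ended. FOXJ1 was also 59.5 CPM in E2 replicate 4, against 5.11 to 17.4 in the other E2 libraries.

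Within E2+TH, KLF9 stood at 115, 117, 33.3, 122, 31.9 and 34.6 CPM in replicates 1 to 6, FKBP5 at 80.9, 90.3, 49.6, 88.9, 31.9 and 34.3 CPM, and PER1 at 96.4, 119, 32.9, 99.1, 12.2 and 13.6 CPM. ZBTB16 stood at 1.36, 1.54 and 2.39 CPM in replicates 1, 2 and 4 and at 0.0527 to 0.31 CPM in the others, and MT1X and MT1G were highest in the same 3 libraries. In E2+TH+Tam replicate 4 KLF9, FKBP5 and PER1 stood at 107, 108 and 53.3 CPM.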
